A study of Mus musculus with 9 samples.

How the data were processed

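The study measured poly(A) RNA by sequencing in the uterus of female CD-1 (ICR) mice, an outbred stock. Per the labels, the mice received corn oil, bisphenol B (BPB) or bisphenol AF (BPAF) by gavage for 28 days, each bisphenol at 300 µg per kg body weight per day, and 3 libraries were made per group from a stranded mRNA kit. The replicate numbers were taken as separate mice, as far as the labels give. The labels state neither the stage of the estrous cycle nor the time of day at collection. Groups were assigned from the sample titles, and all 9 libraries entered the analysis.

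Each deposited file holds 1 value per gene symbol for 1 library, with no unit in its header. The values were read as FPKM, fragments per kilobase of gene length scaled to the library total, which the authors computed before they deposited them. This reading comes from the values themselves. Multiplied by the length of the transcript, the values of genes with a single GENCODE M21 transcript fell within 0.01 of whole multiples of 1 step per library for 84.8% to 86.7% of the values. The aligner, the counting tool, the genome build, the annotation and any filter are not given in the sources used here, so no coordinates are printed. Whether the counting used the strand that the kit preserves is likewise not given.

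From the step, the total behind the scaling was 12620196 to 15616774 reads per library. Whole reads could be recovered for 18223 of 18226 genes searched, that is 99.98%, and for 13670 of the genes tested. Of 34745 lines per file, 126 carried 1 of 59 repeated symbols and were left out, which left 34619 unique symbols. 27 lines carried a symbol that a spreadsheet had turned into a date. The annotation GENCODE M21 held 32732 of the unique symbols, or 94.5%, and was used only for transcript lengths and for which genes overlap. Genes with a unique symbol were kept for testing at 1 FPKM or more in at least 3 libraries, which gave 13743 genes.

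The design had allowed for counts or for normalized values. As the unit was FPKM and not counts, the branch for normalized values was used, and the alternatives that need counts as deposited were not run. Differences were tested with limma 3.58.1 in R 4.3.3 with a mean-variance trend and robust estimation, on log2(FPKM + 1), with all 9 libraries in 1 fit and group as the only term. A fold change is therefore on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. P-values were adjusted over all tested genes by the Benjamini-Hochberg method and genes were called at an adjusted p under 0.05. All tests of a difference between 2 groups were two-sided. The comparisons were BPB against control, BPAF against control, BPAF against BPB, and a joint test of the 3 groups. Values are given as mean ± SD of FPKM over the 3 libraries of a group, and SE and 95% intervals come from limma.

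Of 43 gene lists written for uterine cell types, hormone responses and stress pathways, 39 had at least 5 tested members and were tested with camera in limma at a preset correlation between genes of 0.01, adjusted by the Benjamini-Hochberg method over the lists within a comparison. The lists for ovary and corpus luteum, oviduct and ciliated cells, erythrocytes and eosinophils had too few members. Camera asks whether the genes of a list rank apart from the other tested genes. A list said to rise or fall by camera did so relative to those genes. Each test was repeated with an estimated correlation and with fry, which asks whether a list moves 1 way on balance. For each list the number of members called over all genes and the number called when adjusted over the list alone were counted. A further pair of lists, 15 genes of the urothelium and 9 genes of the muscle and mesenchyme of the lower urinary tract, was written after the values had been seen. Of the 15 urothelial genes 7 reached 1 FPKM in the control mean and 5 stand on a fixed list, and of the 9 lower tract genes 0 and 2.

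The groups, comparisons, tests, fixed lists, processing alternatives and the rule for named genes were chosen before the data were examined. The rule took, in each direction, up to 12 called genes with the largest log2 change (6 for BPAF against BPB) whose 3 libraries did not overlap with the other group, whose mean reached 1 FPKM and whose symbol is a gene name. Where fewer than 5 qualified, genes with the smallest unadjusted p were added until 6 were listed. It also took up to 4 members with the smallest p from each list that passed its test or held a called gene, and always a set of hormone-related genes, of which Esr1, Esr2, Pgr, Gper1, Greb1, Ltf and Mki67 are given and 1 is not reported here.

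The alternatives set in advance were other filters, pseudocounts of 0.1 and 0.01, limma without trend or without robust estimation, the replicate number as a block, other thresholds, the 6 libraries of a comparison alone, and each library left out in turn. After the values had been seen, 6 were added: equal FPKM sums, scaling by median ratios, voom on the recovered reads, the urothelial mean as a covariate, a fit without control 3, BPB 1 and BPAF 1, which shared a trend of expression with gene length, and a replicate block in the 6 BPB and BPAF libraries alone. Same-numbered BPB and BPAF libraries deviated from their group means together, with correlations across genes of 0.343, 0.339 and 0.484, while pairs of BPB and BPAF libraries with other numbers had -0.337 to -0.0721. Deviations within a group sum to 0, so positive values for some pairs force negative ones for others. Because of the positive values, the numbers were taken as a possible pairing of these groups. The labels give only the number, so the pairing comes from the data. It is not shown by them, since control and BPB libraries with unlike numbers matched about as closely. Control 1 and BPB 2 had 0.335, control 2 and BPB 3 0.372, and control 3 and BPB 1 0.448. Agreement of the BPB and BPAF effects was set beside 100 simulated pairs of unchanged groups that share 3 controls. Called genes were set beside 100 further draws, fitted with limma, in which the libraries' deviations from their group means changed places and signs at random. The procedure was tested on simulated data with 200 genes changed among 13743. At 4-fold it recovered 80.5% of them in BPB against control and 80.5% in BPAF against BPB, at 8-fold 97.5% and 95%, and with no change it called 0 genes in each of the 3 comparisons. Unchanged genes called were 8 and 7 at 4-fold and 11 and 11 at 8-fold. The genes were drawn independently of each other and changed in BPB alone. The simulation therefore does not cover genes that vary together, or recovery in BPAF against control. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.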

Results

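Gene expression was measured in 9 uterus libraries, 3 each from mice given corn oil (control), BPB or BPAF. BPB and BPAF are bisphenols used in place of bisphenol A. In BPB the carbon between the phenol rings carries a methyl and an ethyl group, and in BPAF it carries a pair of trifluoromethyl groups. Both were given at the same dose by mass. Per the labels, the study compared the expression profile of each exposed group with the control, and its title names the risk of uterine disease as the concern. The libraries rested on 12620196 (control 3) to 15616774 (BPB 2) reads and held 11614 (control 3) to 13105 (BPAF 1) genes at 1 FPKM or more. The 13 protein-coding mitochondrial genes took 12.0% of the reads in control 3, 2.94% in control 1, 2.92% in control 2 and 4.92% to 7.23% in the exposed libraries. The median SD of log2(FPKM + 1) between the libraries of a group was 0.42 in controls, 0.27 in BPB and 0.35 in BPAF.

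In the BPB uteri, genes known from the lining of the urinary tract stood out as the largest increases, and uterine genes known to be raised by estrogen were among the decreases. Upk1a, which encodes a uroplakin of the urothelial surface, averaged 636 ± 131 FPKM in BPB and 1.06 ± 1.66 FPKM in control (SD, n = 3). Upk3a, another uroplakin, was listed at 0 in all 3 controls and averaged 455 ± 109 FPKM in BPB. It had 323 FPKM in BPAF 1 and was listed at 0 in BPAF 2 and 3. RNA of urinary bladder in the BPB libraries and BPAF 1 is a candidate explanation. Increases of urothelial genes, and of other genes that bladder expresses, can therefore not be assigned to an effect of BPB on the uterus. Sprr2b, a small proline-rich protein gene of the estrogen-stimulated uterine epithelium, averaged 2.96 ± 4.11 FPKM in BPB and 125 ± 44.6 FPKM in control. Lox, the enzyme that cross-links collagen, fell from 61.6 ± 10.96 FPKM in control to 6.90 ± 2.96 FPKM in BPB.

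Of 13743 genes, limma called 351 between BPB and control after Benjamini-Hochberg adjustment, 282 higher and 69 lower in BPB. Under scaling by median ratios the split was 203 higher and 110 lower, so that 64.9% of the calls were higher in place of 80.3%. That scaling moved the median log2 difference of all genes by -0.21, from 0.15 to -0.06, and list medians are to be read against this shift. The 3 libraries of BPB and control did not overlap for 25.6% of the genes, where chance gives 10%.

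Further uroplakin genes and genes of detoxification were among the other large increases. Upk1b (399 ± 114 FPKM in BPB, 1.21 ± 0.704 in control) and Upk2 (330 ± 87.0 and 0.399 ± 0.409) encode uroplakins. Krt15 is a basal keratin, Ivl encodes involucrin of cornified envelopes, and Snx31 a sorting nexin that binds uroplakins. P2rx1, an ATP-gated channel of visceral smooth muscle, rose by 6.41 on the log2 scale (SE 0.83) with an adjusted p of 0.0143 in limma. The glutathione transferases Gstm1 (857 ± 212 FPKM in BPB, 14.6 ± 10.4 in control) and Gsta4 (725 ± 32.6 and 13.7 ± 9.29), the pseudogene Gstm2-ps1 and the flavin monooxygenase Fmo5 completed the 12 largest increases. Gstm1 and Gstm2-ps1 have near-identical copies, so their values are uncertain.

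Genes of the urothelium, collected in a list of 15 written after the values were seen, followed the libraries and not only the groups. The mean log2(FPKM + 1) of this list was 5.84, 6.49 and 6.68 in BPB 1, 2 and 3, 5.61 in BPAF 1, 0.66 in BPAF 2, 0.56 in BPAF 3 and 0.50 to 1.17 in the controls. In BPB against control 13 of the 15 genes rose, 15 when adjusted over the list alone, among them Gata3 (14.96 ± 4.09 FPKM against 0.229 ± 0.127 in control). Camera in limma gave an adjusted p of 2.59e-13 for this list, and adjusted p = 0.492 with an estimated correlation. A list of 9 genes of lower urinary tract muscle and mesenchyme averaged 2.77, 3.29 and 3.07 in the BPB libraries, 1.34 in BPAF 1, 0.28 and 0.46 in BPAF 2 and 3, and 0.20 to 0.25 in the controls. It too was written after the values were seen, so the p-values of both lists partly restate how they were chosen. In BPB against control 8 of these 9 genes rose, 9 when adjusted over the list alone, with Pitx1 at 14.4 ± 2.92 FPKM against 0.0341 ± 0.0591 in control (camera in limma, adjusted p = 4.70e-14, and adjusted p = 0.385 with an estimated correlation).

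**Figure D1:**
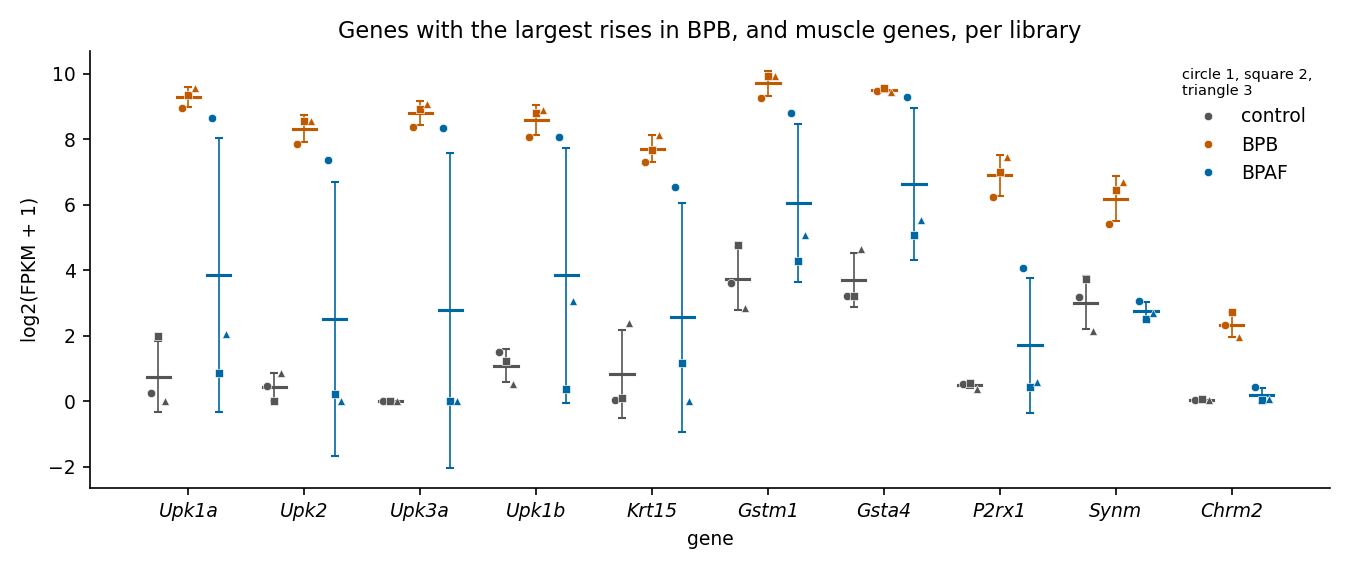
Expression of urothelial, detoxification and smooth muscle genes in each library, as log2(FPKM + 1) by group, with circles, squares and triangles for replicates 1, 2 and 3, bars for the group mean and error bars for the SD (n = 3). The uroplakin Upk1a is high in the 3 BPB libraries and in BPAF 1, with group means of 636 FPKM in BPB, 134 in BPAF and 1.06 in control, while Synm is high in the 3 BPB libraries alone.

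Fixed lists of detoxification and of muscle rose in BPB, and bladder RNA was not excluded as a source of these rises. Of 21 tested genes of xenobiotic metabolism 5 rose, 12 when adjusted over the list alone, including Gsta2 (10.4 ± 0.814 FPKM against 0.277 ± 0.0708) and the glucuronosyltransferase Ugt2b34 (13.6 ± 7.47 against 0.252 ± 0.254). The list had a median of 1.30, a camera adjusted p of 7.70e-07 in limma and adjusted p = 0.505 with an estimated correlation. Its mean over the genes was 4.23 to 4.40 in the BPB libraries, 4.15 in BPAF 1, 2.46 in BPAF 2, 3.24 in BPAF 3 and 2.39 to 2.66 in the controls. Among 20 smooth muscle genes 3 rose, 3 also when adjusted over the list alone: Synm, an intermediate filament protein (77.3 ± 32.0 FPKM against 7.93 ± 4.45), Synpo2, an actin-binding protein, and Casq2, a calcium store protein. The median was 1.03, with a camera adjusted p of 7.84e-05 in limma and adjusted p = 0.505 with an estimated correlation. Unlike the urothelial mean, the smooth muscle mean of BPAF 1 (6.36) lay below those of the controls (6.38 to 7.14) and of BPB (7.50 to 8.09).

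Krt4, Trp63, Krt15 and Ivl rose among 11 genes of stratified squamous epithelium, 6 genes when adjusted over the list alone (median 2.66, camera in limma adjusted p = 0.0111, and adjusted p = 0.505 with an estimated correlation). Krt15 and Trp63 also belong to the urothelial list. The mesothelium list rose (7 tested, median 0.67, camera in limma adjusted p = 0.0209, and adjusted p = 0.505 with an estimated correlation) with Upk1b and Upk3b as its 2 called genes, 2 also when adjusted over the list alone, and both are on the urothelial list. Myh2, a fast myosin, and Ckm, muscle creatine kinase (60.0 ± 8.80 FPKM against 4.72 ± 1.08), rose among 7 skeletal muscle genes, 2 also when adjusted over the list alone (median 0.97, camera in limma adjusted p = 0.0308, and adjusted p = 0.505 with an estimated correlation). No adipocyte gene was called among 13, 1 rose when adjusted over the list alone, and the list had a median of 1.2 and a camera adjusted p of 0.0346 in limma, with adjusted p = 0.672 with an estimated correlation. The squamous list averaged 4 to 4.13 in BPB, 3.57 in BPAF 1, 1.06 and 0.44 in BPAF 2 and 3, and 0.88, 0.97 and 2.81 in controls 1, 2 and 3. The mesothelium list averaged 3.25 to 4.03 in BPB, 3.34, 1.26 and 2.35 in BPAF and 1.33 to 1.81 in controls, and the skeletal muscle list 3.02 to 3.89, 2.56, 1.92 and 1.01, and 2.30 to 2.67. The adipocyte list averaged 4.57, 4.06 and 2.43 in BPB 1, 2 and 3, 4.09, 0.77 and 4.11 in BPAF and 2.39 to 2.44 in controls. Without BPB 1 or 3 the adipocyte median was 0.68 or 1.86, and without BPB 2 that of mesothelium was 1.13.

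A further 3 lists rose in BPB. The WNT ligand gene Wnt2 and Nkd1, an inhibitor that WNT induces, rose among 20 WNT genes, 2 also when adjusted over the list alone (median 0.71, camera in limma adjusted p = 0.0443, and adjusted p = 0.505 with an estimated correlation). In the circadian list of 16 genes 3 rose and 8 rose when adjusted over the list alone, with 1 that fell: Nr1d1 (26.6 ± 11.8 FPKM against 2.82 ± 1.03 in control) and Nr1d2 (20.2 ± 5.42 against 6.99 ± 2.21) encode the REV-ERB repressors, and Dbp (9.37 ± 3.87 against 1.52 ± 0.242) a clock output factor. Its camera adjusted p in limma was 0.0236, with adjusted p = 0.521 with an estimated correlation. The list of luteal-phase genes rose with a median of 1.34 and no called member among 17 (camera in limma adjusted p = 0.0250, and adjusted p = 0.556 with an estimated correlation), and 3 rose and 1 fell when adjusted over the list alone. Without BPB 1 its median was 0.83.

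Genes of the estrogen-stimulated uterus were among the decreases in BPB. Of 27 tested estrogen-induced genes 3 fell, Sprr2b, Sprr2g and Oxtr, the oxytocin receptor gene (2.18 ± 1.14 FPKM against 36.96 ± 20.99 in control). When adjusted over the list alone 13 fell and 2 rose. The median was -1.72, with a camera adjusted p of 5.54e-07 in limma and adjusted p = 0.505 with an estimated correlation. Inhbb, an activin subunit on this list, averaged 16.3 ± 10.98 FPKM in BPB and 231 ± 111 in control and did not pass (limma, adjusted p = 0.0536). Other large decreases were in Tmprss11d, an airway-type serine protease, Nppc, the C-type natriuretic peptide gene (0.153 ± 0.266 against 19.98 ± 13.7), Akr1c14, a hydroxysteroid dehydrogenase, Uox, urate oxidase, Trim15 and Lrg1. Sprr2b and Sprr2g belong to a family of near-identical copies, so their values are uncertain.

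Lists of matrix genes and of some immune functions fell by camera, with few single genes called. Lox was the called gene among 24 fibrillar matrix genes, with 4 that fell and 1 that rose when adjusted over the list alone (median -1.07, camera in limma adjusted p = 2.23e-06, and adjusted p = 0.505 with an estimated correlation). Col1a2 averaged 85.3 ± 19.4 FPKM in BPB and 337 ± 201 in control and did not pass (limma, adjusted p = 0.0735). Adamts1 and Adamts4, proteases that cleave proteoglycans, fell among 14 matrix-degrading enzymes, 2 also when adjusted over the list alone (median -0.42, camera in limma adjusted p = 0.00607, and adjusted p = 0.505 with an estimated correlation). All 25 interferon-stimulated genes had lower means in BPB, 1 fell, Bst2 or tetherin (103 ± 26.8 against 464 ± 270), and 14 fell when adjusted over the list alone. That list had a median of -2.04, a camera adjusted p of 9.33e-16 in limma and adjusted p = 0.505 with an estimated correlation, and its mean was 6.18 in control 1 against 2.98 and 3.31 in controls 2 and 3. Il1a and Ccl7 fell among 23 chemokines and cytokines, 4 when adjusted over the list alone (camera in limma adjusted p = 3.79e-06, and adjusted p = 0.505 with an estimated correlation). Pglyrp1, a peptidoglycan recognition protein, and Rtp4, an interferon-induced gene, were among the 12 largest decreases. Without control 1 the interferon median was -0.99, and without control 2 the medians were -0.64 for fibrillar matrix and 0.23 for matrix-degrading enzymes.

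Lists of macrophages (16 tested, median -0.52), neutrophils (7, median -1.33), complement and antimicrobial secretions (22, median -0.63), mitosis (26, median -1.06), immediate early genes (18, median -0.11), heat shock (20, median -0.38) and cholesterol synthesis (19, median -0.78) also ranked below the other genes by camera in limma, with adjusted p from 8.85e-12 for mitosis to 0.0104 for immediate early genes, and adjusted p = 0.505 with an estimated correlation for each. T and natural killer cell genes (12, median -0.21, adjusted p = 0.0209 by camera in limma) and DNA replication (22, median -0.33, adjusted p = 0.00607) had an adjusted p of 0.585 and 0.672 with an estimated correlation. Single genes called in these lists were Cyp51, a sterol demethylase that fell from 32.4 ± 6.97 to 9.26 ± 0.509 FPKM, Sdf2l1, a chaperone of the endoplasmic reticulum that fell from 41.3 ± 7.36 to 14.03 ± 6.75 FPKM, and the complement component C7, which rose from 0.077 ± 0.069 to 5.90 ± 1.72 FPKM. When adjusted over the list alone 3 cholesterol genes, 4 heat shock genes, 3 immediate early genes, 3 complement genes and 1 neutrophil gene fell, and 2 complement genes and 1 heat shock gene rose. Medians nearer 0 were -0.05 for T and natural killer cells, -0.32 for complement and -0.44 for cholesterol without control 1, 0.03 for immediate early genes and -0.07 for DNA replication without control 2, and -0.29 for macrophages and -0.18 for heat shock without BPB 2.

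Single genes were called in lists that did not pass. They were Pi16, a fibroblast gene, Cldn4, a tight junction gene (82.7 ± 9.35 FPKM in BPB against 12.2 ± 0.82), Id3, a target of BMP signalling, the channel genes Scnn1g and Ano1, the prostaglandin synthase gene Ptgs1 and the muscarinic receptor gene Chrm2, these 7 higher in BPB, with adjusted p of 0.0105 to 0.0423 in limma. Oxtr, which fell, belongs to the contraction list as well. B and plasma cell (camera in limma, adjusted p = 0.212), mast cell (0.224) and MHC class II genes (0.612) did not pass. Stroma (camera in limma, adjusted p = 0.576), uterine epithelium (0.212), TGF-beta signalling (0.541), ion channels (0.602), contraction (0.709), oxidative phosphorylation (0.473), mitochondrially encoded (0.486) and ribosomal protein genes (0.3) did not pass.

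The steroid receptor genes did not pass in BPB. Esr1, the main estrogen receptor gene of the uterus, averaged 16 ± 3.66 FPKM in BPB and 26.1 ± 4.81 in control (limma, adjusted p = 0.311), and Pgr, the progesterone receptor gene, 14.3 ± 7.32 against 46.6 ± 12.1 (limma, adjusted p = 0.0672). Adjusted p in limma was 0.669 for Gper1, 0.408 for Greb1, 0.350 for Ltf and 0.165 for Mki67, a proliferation marker. Esr2 stayed below the level for testing, with group means of 0.015 FPKM in control and 0.138 in BPB.

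**Figure D2:**
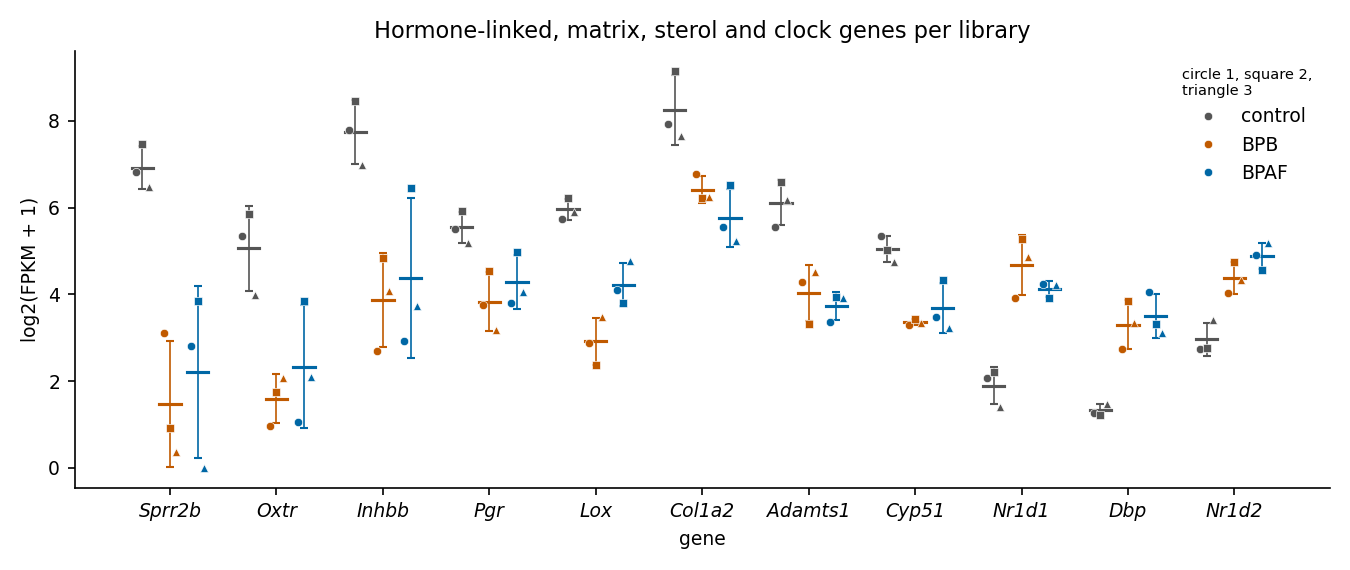
Expression of hormone-responsive, matrix, cholesterol and clock genes in each library, as log2(FPKM + 1) by group, with circles, squares and triangles for replicates 1, 2 and 3, bars for the group mean and error bars for the SD (n = 3). Sprr2b means were 125 FPKM in control, 2.96 in BPB and 6.44 in BPAF, and Nr1d1 means were 2.82, 26.6 and 16.5 FPKM.

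The count for BPB rested on single libraries: without control 1, 2 or 3 it was 1, 99 or 71 genes, and without BPB 1, 2 or 3 it was 221, 1 or 3 genes. With each library left out in turn 12 of the 23 list calls were kept, and the luteal (adjusted p up to 0.139), matrix-degrading (0.164), mesothelium (0.0620), adipocyte (0.253), squamous (0.101), skeletal muscle (0.142), T and natural killer cell (0.175), complement (0.0562), DNA replication (0.141), WNT (0.132) and circadian (0.102) lists were lost without at least 1 of the 6 libraries of the comparison, by camera in limma.

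In the BPAF uteri 3 genes differed from control, and all 3 moved the same way in BPB. Zbtb9, a zinc finger gene, averaged 0.454 ± 0.0570 FPKM in BPAF, 0.421 ± 0.0934 in BPB and 7.09 ± 0.332 in control (SD, n = 3), and fell in BPAF by 2.48 on the log2 scale (SE 0.19, adjusted p = 0.00306 in limma). Ggnbp1, a gene known from the testis, rose from 0.369 ± 0.103 FPKM in control to 4.66 ± 0.762 in BPAF and 4.20 ± 0.786 in BPB (adjusted p = 0.0284 and 0.0105 in limma). Pnoc, which encodes the neuropeptide precursor prepronociceptin, fell from 2.54 ± 0.426 FPKM to 0.0332 ± 0.0319 in BPAF and 0.108 ± 0.0268 in BPB (adjusted p = 0.0287 and 0.0109). Zbtb9 and Ggnbp1 overlap on the same strand in GENCODE M21, so their values are uncertain: the recovered reads of Zbtb9 were 246 to 315 in controls and 12 to 22 in exposed libraries, and those of Ggnbp1 33 to 56 and 427 to 614. Pnoc had 66 to 90 recovered reads in controls and 0 to 4 in exposed libraries. Fbxo16 went the other way, with 3 to 8 and 17 to 54. Whether the change of Pnoc is tied to that of Fbxo16 was not tested.

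**Figure D3:**
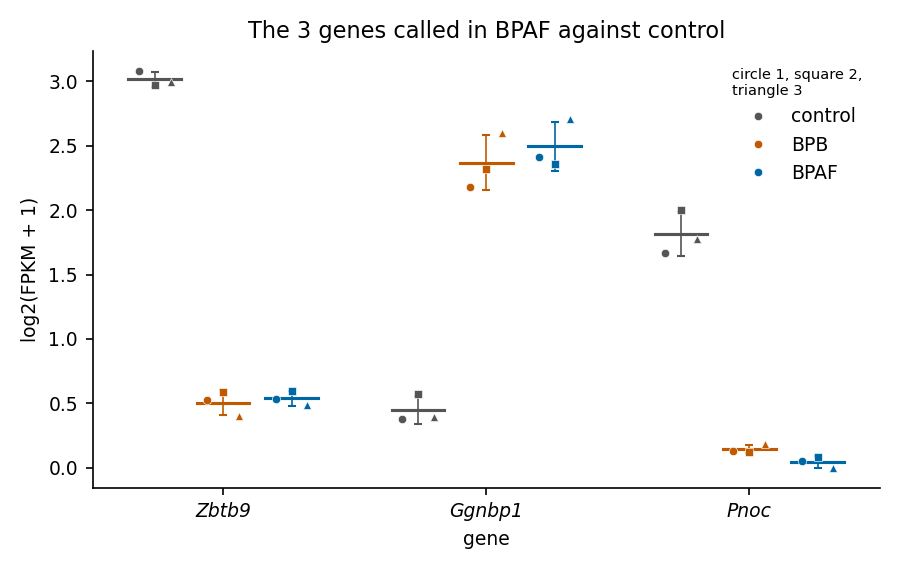
Expression of Zbtb9, Ggnbp1 and Pnoc in each library, as log2(FPKM + 1) by group, with circles, squares and triangles for replicates 1, 2 and 3, bars for the group mean and error bars for the SD (n = 3). The control mean of Zbtb9 was 7.09 FPKM, against 0.421 in BPB and 0.454 in BPAF.

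Of 13743 genes, limma called 3 between BPAF and control after Benjamini-Hochberg adjustment, 1 higher and 2 lower, and 1757 had an unadjusted p under 0.05. Scaling by median ratios called 4, 1 higher and 3 lower, and moved the median of all genes by -0.25. The libraries did not overlap for 16.8% of the genes, where chance gives 10%. The genes next in order did not pass. Nr1d2, Dbp and Nr1d1 averaged 28.9 ± 6.16, 10.8 ± 4.33 and 16.5 ± 2.04 FPKM in BPAF and 6.99 ± 2.21, 1.52 ± 0.242 and 2.82 ± 1.03 in control (limma, adjusted p = 0.134, 0.136 and 0.147). Plxnb1, a semaphorin receptor gene, and B4galnt4, a glycosyltransferase gene, had an adjusted p of 0.133 and 0.136 in limma. On the lower side were Trim15, Ppp1r3c, a regulator of glycogen synthesis (7.32 ± 0.803 FPKM against 25.4 ± 4.26), the heat shock gene Hspa1b and Il1f9, an epithelial cytokine, with adjusted p of 0.102 to 0.129 in limma. Hspa1b shares reads with its near-identical copy Hspa1a, and its value is uncertain.

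Lists of estrogen-induced, fibrillar matrix and smooth muscle genes had lower medians in BPAF than in control, with 0 members called over all genes by limma. All of the lists named here for BPAF were tested by camera in limma with Benjamini-Hochberg adjustment. Of 27 estrogen-induced genes none was called and 3 fell when adjusted over the list alone, with a median of -1.19 (adjusted p = 7.21e-14, and adjusted p = 0.247 with an estimated correlation). Sprr2b averaged 6.44 ± 6.70 FPKM in BPAF against 125 ± 44.6 (limma, adjusted p = 0.216), and Oxtr 5.95 ± 6.62 against 36.96 ± 20.99 (limma, adjusted p = 0.284). Of 24 fibrillar matrix genes 8 fell when adjusted over the list alone and 0 over all genes, with a median of -1.22 (adjusted p = 4.48e-20 in limma, and adjusted p = 0.247 with an estimated correlation). Col1a2 averaged 57.4 ± 28.6 FPKM against 337 ± 201, and Col3a1 125 ± 16.2 against 535 ± 274. The 20 smooth muscle genes all had lower means in BPAF than in control, with a median of -0.83, 0 called over all genes and 0 when adjusted over the list alone (adjusted p = 3.48e-13 in limma, and adjusted p = 0.356 with an estimated correlation). Myh11, smooth muscle myosin, averaged 162 ± 70.9 FPKM against 389 ± 136. Without control 2 the fibrillar matrix median was -0.75, and without BPAF 3 the smooth muscle median was -0.43.

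Of 19 genes of cholesterol synthesis 1 fell when adjusted over the list alone (median -0.98, limma adjusted p = 8.84e-14, and adjusted p = 0.356 with an estimated correlation). The interferon list had a median of -1.50 with 0 genes called over all genes and 0 when adjusted over the list alone (limma adjusted p = 3.16e-16, and adjusted p = 0.358 with an estimated correlation). Its mean was 2.42 to 3.14 in BPAF, 6.18 in control 1 and 2.98 and 3.31 in controls 2 and 3, and without control 1 its median was -0.49. Of 23 chemokines 3 fell when adjusted over the list alone, with Ccl2 at 0.495 ± 0.336 against 6.33 ± 4.61 FPKM (limma adjusted p = 2.66e-07, and adjusted p = 0.356 with an estimated correlation). Lists of neutrophils (median -1.60), heat shock genes (-0.18), complement (-0.38), macrophages (-0.35), matrix-degrading enzymes (-0.24), immediate early genes (-0.11), skeletal muscle (-0.39), steroid metabolism (-0.27) and mitosis (-0.06) ranked below the other genes by camera in limma, with adjusted p from 8.19e-05 to 0.0412. The median of all genes was 0.21, and of the mitotic genes 11 had higher and 15 lower means than in control, so that list is not shown to fall from control. The adjusted p of these lists was 0.247 to 0.813 with an estimated correlation, and when adjusted over the list alone 1, 2, 1, 0, 3, 1, 0, 0 and 0 of their genes fell, in that order. Without control 1 the medians were -0.95 for neutrophils and 0.0046 for complement, without control 2 it was 0.23 for matrix-degrading enzymes, without BPAF 2 0.20 for macrophages, and without BPAF 3 -0.53 for cholesterol, 0.01 for skeletal muscle and 0.52 for mitosis.

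On the higher side, 29 of 30 ribosomal protein genes had higher means in BPAF than in control (median 0.53, limma adjusted p = 0.000116, and adjusted p = 0.539 with an estimated correlation). The luteal list rose with a median of 1.29 (limma adjusted p = 0.0341, and adjusted p = 0.677 with an estimated correlation). Its mean was 3.60, 2.92 and 4.56 in BPAF 1, 2 and 3 and 2.13 to 3.05 in controls, and without BPAF 3 its median was 0.92 and its camera adjusted p in limma 0.391. WNT genes rose with 0.72 (0.0120, and adjusted p = 0.362 with an estimated correlation) and DNA replication genes with 0.66 (0.0224, and adjusted p = 0.813 with an estimated correlation). When adjusted over the list alone 0 ribosomal, 4 luteal, 0 WNT and 1 DNA replication genes rose and 1 luteal gene fell. Mcm7, a subunit of the replicative helicase, averaged 16.1 ± 4.72 FPKM against 5.77 ± 2.45 (limma, adjusted p = 0.230). The mean of the DNA replication list was 4.03 in BPAF 2, 3.25 in BPAF 1, 2.07 in BPAF 3 and 2.10 to 2.99 in the controls, and without BPAF 2 its median was 0.20. Urothelial genes did not pass in BPAF, where Upk1a averaged 134 ± 230 FPKM, with 400 FPKM in BPAF 1, 0.838 in BPAF 2 and 3.14 in BPAF 3 (urothelial list, camera in limma, adjusted p = 0.0776).

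In limma, adjusted p in BPAF against control was 0.676 for Esr1, 0.304 for Pgr, 0.893 for Gper1, 0.571 for Greb1, 0.656 for Ltf and 0.588 for Mki67. Pgr averaged 19.7 ± 9.37 FPKM in BPAF and Esr1 21.2 ± 7.54, and Esr2 again stayed below the level for testing, at 0.0921 FPKM.

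The count for BPAF was 1, 6 or 10 without control 1, 2 or 3, 1 without any of BPB 1, 2 or 3, and 1, 2 or 1 without BPAF 1, 2 or 3, and it was 0 with the 6 libraries of the comparison alone, where 1173 genes had an unadjusted p under 0.05. With each library left out 9 of the 19 list calls were kept, and by camera in limma those for luteal genes (adjusted p up to 0.391), steroid metabolism (0.0513), matrix-degrading enzymes (0.254), skeletal muscle (0.102), macrophages (0.615), complement (0.175), immediate early genes (0.0526), WNT (0.102), DNA replication (0.866, with the sign turned, without BPAF 2) and mitosis (0.461, and 0.00777 with the sign turned without BPAF 3) were lost without control 1, 2 or 3 or BPAF 1, 2 or 3.

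Compared directly at the same dose by mass, genes of smooth and skeletal muscle were among those lower in BPAF than in BPB. Synm averaged 5.84 ± 1.37 FPKM in BPAF and 77.3 ± 32.0 in BPB (SD, n = 3), a difference of -3.44 on the log2 scale (95% interval -4.46 to -2.42, adjusted p = 0.0414 in limma). Pitx1, a transcription factor gene of the hindlimb and lower body, differed by -3.33 (-4.28 to -2.39), and Hspb6, a small heat shock protein of muscle, by -2.89 (-3.86 to -1.92). Npy6r, Kcnf1 and Fam129a were the other genes with the largest differences, at -2.87, -2.82 and -2.79 and adjusted p of 0.0414 to 0.0438 in limma. Chrm2, a muscarinic receptor gene, was also lower, at 0.148 ± 0.186 against 4.20 ± 1.36 FPKM. Pitx1 and Chrm2 belong to the lower urinary tract list, whose mean was 2.77 to 3.29 in BPB and 0.20 to 0.25 in controls. Bladder tissue in the BPB libraries would give such differences as well, so they cannot be assigned to the compounds.

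Of 13743 genes, limma called 33 between BPAF and BPB after Benjamini-Hochberg adjustment, all 33 lower in BPAF, and 927 had an unadjusted p under 0.05. Scaling by median ratios called 46, all lower. Same-numbered BPB and BPAF libraries deviated together, and with a replicate block limma called 0 genes (852 with an unadjusted p under 0.05), or 0 (1788) in the 6 libraries of the comparison alone. All 16 list calls below were kept under both blocks, and antigen presentation by MHC class II passed in addition with the replicate block in 9 libraries (camera in limma, adjusted p = 0.0318 in place of 0.173). With an estimated correlation or with fry 0 lists passed. Of the 10 splits of these 6 libraries 7, the real one among them, gave as many lists (highest other 18), so the number of lists does not set the real groups apart. The libraries did not overlap for 13% of the genes, where chance gives 10%. The genes with the smallest p on the higher side, Tmem86a, Prom1, Mogat2, Bzw1, Foxp1 and Lox, did not pass (limma, adjusted p = 0.116 to 0.280), and Lox averaged 18.4 ± 6.92 FPKM in BPAF and 6.90 ± 2.96 in BPB.

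Among 20 smooth muscle genes Synm, Synpo2 and Casq2 fell and 18 fell when adjusted over the list alone, with a median of -1.81 (camera in limma, adjusted p = 1.94e-30, and adjusted p = 0.230 with an estimated correlation). The list mean was 6.36, 6.28 and 5.09 in BPAF 1, 2 and 3, 7.50 to 8.09 in BPB and 6.38 to 7.14 in control, so that BPB lay above and BPAF at or below the controls. Skeletal muscle genes (median -1.66, Myh2 fell, 5 when adjusted over the list alone) had a camera adjusted p of 2.72e-08 in limma, and adjusted p = 0.230 with an estimated correlation. Of 16 uterine contraction genes Chrm2 fell, 1 also when adjusted over the list alone (median -0.27, camera in limma adjusted p = 0.0154, and adjusted p = 0.726 with an estimated correlation). Chrm2 also belongs to the lower urinary tract list, of which 6 of 9 genes fell, 8 when adjusted over the list alone (median -2.13, camera in limma adjusted p = 3.83e-25, and adjusted p = 0.0955 with an estimated correlation). That list was written after the values were seen, so its count and p-value partly restate how it was chosen.

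Further lists fell, with 0 genes called over all genes: squamous epithelium (median -2.09), xenobiotic metabolism (-1.11), mesothelium (-0.80), adipocytes (-0.50), fibrillar matrix (-0.52) and TGF-beta signalling (-0.31). Their camera adjusted p in limma was 8.87e-07, 1.08e-07, 0.0108, 0.0188, 0.000619 and 0.0243, and the adjusted p was 0.447 to 0.852 with an estimated correlation. When adjusted over the list alone 6, 8, 2, 1, 2 and 0 of their genes fell, in that order, and 1 matrix gene rose. Without BPAF 2 the medians were -0.61 for xenobiotic metabolism, -0.25 for mesothelium and 0.61 for adipocytes. The urothelial list itself, written after the values were seen, had a median of -3.92 with 0 genes called over all genes and 15 that fell when adjusted over the list alone (camera in limma, adjusted p = 5.67e-21, and adjusted p = 0.344 with an estimated correlation). Upk1a differed by -5.44 with a 95% interval of -9.13 to -1.74 (limma, adjusted p = 0.373).

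Lists higher in BPAF than in BPB had no called member and 0 when adjusted over the list alone. All 26 mitotic and all 22 DNA replication genes had higher means in BPAF (medians 0.96 and 0.99), with Top2a, topoisomerase of the mitotic chromosome, at 16.8 ± 10.5 against 4.48 ± 1.39 FPKM. Camera in limma gave adjusted p of 1.39e-10 and 8.64e-10, and adjusted p = 0.626 with an estimated correlation for both. The mitotic mean was 2.95, 3.44 and 1.51 in BPAF 1, 2 and 3 and 1.40 to 2.06 in BPB, and the replication mean 3.25, 4.03 and 2.07 against 1.96 to 2.44, so that BPAF 3 lay within the range of BPB in both. Without BPAF 2 the medians were 0.54 for both lists, and without BPAF 3 they were 1.52 and 1.53. All 12 T and natural killer cell genes were higher (median 0.94, limma adjusted p = 3.31e-05, and adjusted p = 0.626 with an estimated correlation), with Gzma at 13.04 ± 11.1 against 2.99 ± 1.34 FPKM. B and plasma cell (median 1.08), endothelial (0.39), interferon (0.57) and ribosomal protein genes (0.32) passed at adjusted p of 0.00479, 0.00715, 0.0351 and 0.00261 by camera in limma, with adjusted p of 0.626, 0.731, 0.996 and 0.731 with an estimated correlation. Without BPAF 3 the medians were 0.48 for T and natural killer cells and 0.14 for endothelium, and without BPB 3 it was 0.18 for ribosomal proteins.

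Genes of hormone response were not shown to differ between the bisphenols, and their intervals were wide. The difference was 0.34 for Esr1 (95% interval -0.37 to 1.05), 0.45 for Pgr (-0.48 to 1.39), 0.75 for Sprr2b (-1.42 to 2.91), -0.25 for Gper1 (-1.16 to 0.65), 0.25 for Greb1 (-1.25 to 1.75), 1.21 for Ltf (-2.00 to 4.41) and 0.90 for Mki67 (-0.34 to 2.15). For the genes called in BPAF against control it was 0.03 for Zbtb9 (-0.39 to 0.46), 0.13 for Ggnbp1 (-0.36 to 0.61) and -0.10 for Pnoc (-0.54 to 0.34). The estrogen-induced list did not pass, with a median of 0.50, a camera direction of the opposite sign and an adjusted p of 0.765 in limma.

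**Figure D4:**
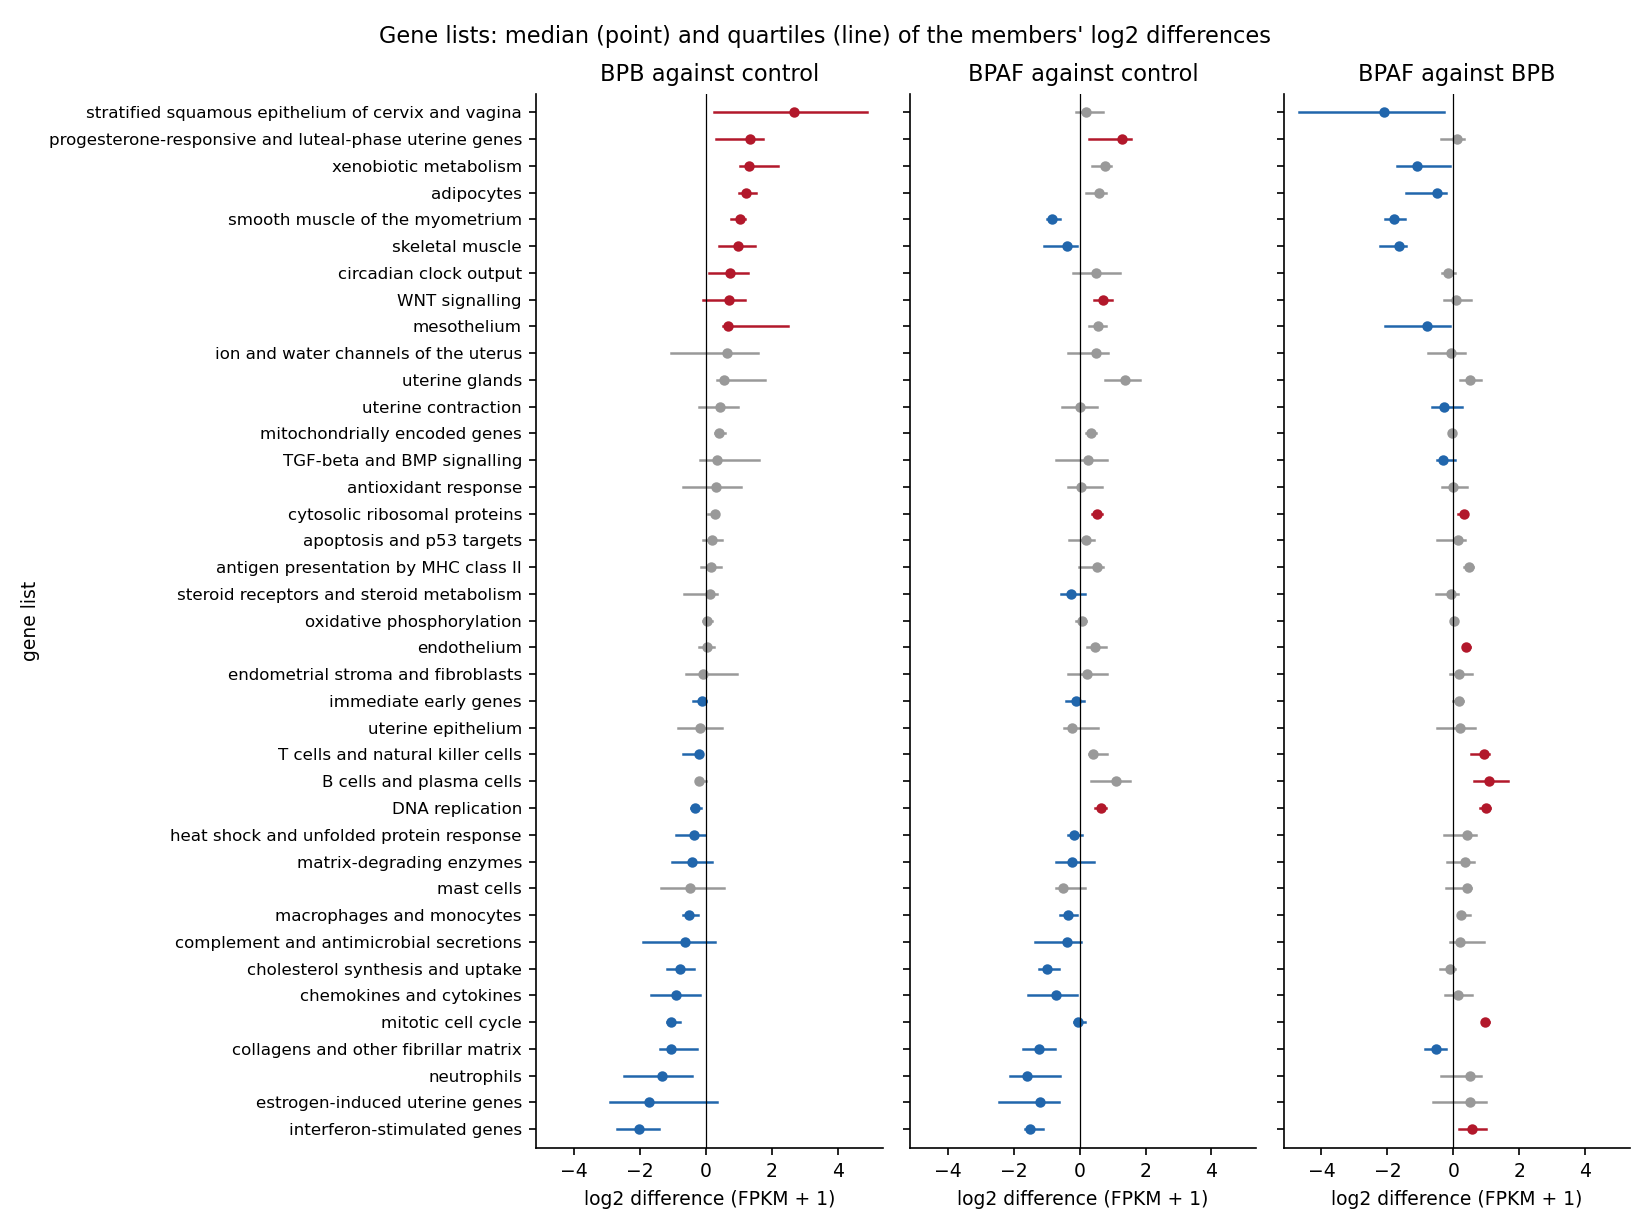
Median log2 difference (point) and quartiles (line) of the tested genes of 39 fixed lists in the 3 comparisons, in log2(FPKM + 1), with lists past camera's adjusted p of 0.05 in red when up and blue when down, and others in grey. Estrogen-induced genes lie at -1.72 in BPB and -1.19 in BPAF against control, and smooth muscle genes at 1.03 and -0.83.

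The count of 33 became 0 without any of control 1, 2 or 3, BPB 2 or 3 or BPAF 2 or 3, 234 without BPAF 1, of which 229 were lower in BPAF, and 0 with voom on the recovered reads, with 563 to 1189 genes at an unadjusted p under 0.05. With each library left out 9 of the 16 list calls were kept, and by camera in limma those for endothelium (adjusted p up to 0.335), mesothelium (0.121), adipocytes (0.551, with the sign turned, without BPAF 2), interferon (0.296), ribosomal proteins (0.0633), TGF-beta (0.0915) and contraction (0.0955) were lost without at least 1 of control 3, BPB 1, 2 or 3 or BPAF 1, 2 or 3.

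In the joint test of the 3 groups limma called 116 genes after Benjamini-Hochberg adjustment, and 0 with a replicate block (1735 with an unadjusted p under 0.05). The BPB and BPAF differences from control correlated across genes with Pearson's r of 0.707 and Spearman's rho of 0.660. Genes are not independent replicates, and unchanged groups sharing these controls gave an r of 0.505 on average in 100 simulations (95% of them between -0.36 and 0.94) and a rho of 0.476. The covariance was 0.296 against a simulated 0.103 (95% between -0.0388 and 0.298), a difference of 0.192. Of all genes 77.7% had the same sign, against 68.4% in the simulations (33.5% to 88.4%). The observed r, rho, covariance and same-sign share all lay within the simulated ranges, which were -0.39 to 0.91 for rho. Of the 282 genes higher in BPB 265 had the same sign in BPAF, where their median was 0.68 against 1.99 in BPB, and all 69 lower genes had the same sign (-1.55 against -2.07). Those are 94.0% and 100%, and among as many genes of smallest p in 100 draws of unchanged groups with shared controls the share was 82.3% (95% of draws from 17.6% to 100%) and 82.6% (14.1% to 100%). The single gene called higher in BPAF and both genes called lower were called in BPB too, where independent lists would share 0.0205 and 0.01. That value leaves out the shared controls, and the 100 draws, in which limma called no gene in both, leave out any effect, so neither shows what unrelated effects would share here. With 3 controls the controls could not be split into parts of at least 2 libraries, so part of the likeness may come from the shared controls.

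**Figure D5:**
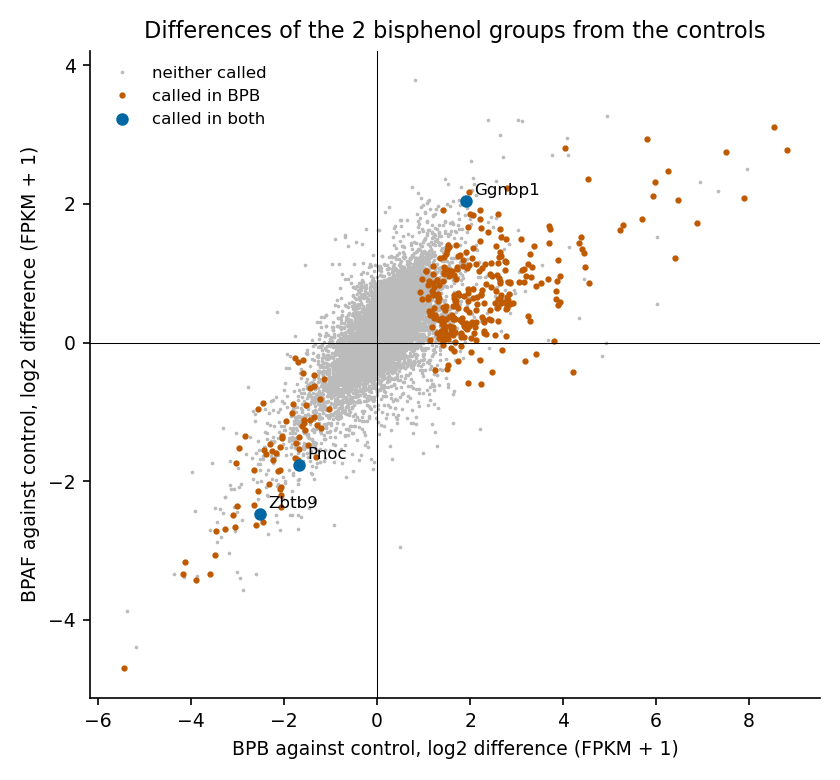
Log2 difference from control of each tested gene in BPB (x axis) and BPAF (y axis), in log2(FPKM + 1), with 1 point per gene. Genes called in BPB lie at medians of 1.99 and -2.07 on the x axis and 0.68 and -1.55 on the y axis.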

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

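Chosen only after the values were seen were equal FPKM sums, median-ratio scaling, voom on the recovered reads, the urothelial mean as a covariate, the fit without control 3, BPB 1 and BPAF 1, and the block in 6 libraries. Counts of genes depended on the setting more than directions did. The 67 differences called for named genes changed sign in 0 of 1128 values under the alternatives set in advance and in 6 of 343 under those added, and the 233 not called in 12 of 3911 and 24 of 1234. The 0 was in part fixed by the rule, since genes named for libraries that do not overlap cannot change sign when a library is left out. No list that passed had a median of the other sign under another scaling, and the correlation of the effects, 0.707, ranged from 0.554 (without BPAF 1) to 0.812 (genes past the joint test only). At 12620196 to 15616774 reads per library, weakly expressed genes rest on few reads. A lone library does not arise, since 2 remain in a group when 1 is left out. Size factors, upper quartile factors and count-based tests, listed for counts, were not run because the deposited values are FPKM.

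The following counts of called genes, all from limma, are given for BPB against control (351), BPAF against control (3), BPAF against BPB (33) and the joint test (116). Without a filter they were 163, 4, 11 and 56, and at 5 FPKM or more in 3 libraries, where fewer genes are tested, 151, 0, 0 and 8. A pseudocount of 0.1 gave 152, 2, 0 and 2, and 0.01 gave 66, 2, 0 and 2. An adjusted p under 0.1 gave 774, 3, 66 and 325. With only the 6 libraries compared, 503, 0 and 0 genes were called. Equal FPKM sums gave 209, 1, 8 and 35, and voom 27, 2, 0 and 1. The urothelial covariate gave 0, 1, 0 and 0, and the fit without control 3, BPB 1 and BPAF 1 gave 290, 0, 229 and 247. Median-ratio scaling gave 313, 4 and 46, and leaving out trend or robust estimation gave 332 and 364 in BPB against control. Genes with an unadjusted p under 0.05, where limma called 0, numbered 1020 and 534 at 5 FPKM, 897 and 857 with the pseudocounts, 1173 and 1118 with 6 libraries, 961 with voom, 598, 336 and 843 with the covariate, and 1990 in BPAF against control in the fit without 3 libraries. The cause was not tested, except where fewer genes or libraries entered.

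With each library left out in turn the counts ranged from 1 (without control 1 or BPB 2) to 427 (without BPAF 1), from 1 to 10 (without control 3), from 0 to 234 (without BPAF 1), and in the joint test from 0 (without control 1) to 310 (without BPAF 1). Lists past camera ranged over 17 to 23, 16 to 22 and 13 to 17. With an estimated correlation 0 of the 23, 19 and 16 lists passed, and with fry 0. Under the urothelial covariate the log2 difference between BPB and control turned to -0.28 for Upk3a, -0.13 for Upk2, -0.015 for Krt15, -0.46 for Ivl, -0.31 for Snx31 and -0.16 for Upk3b, genes of which some make up the covariate. That covariate was 5.84 to 6.68 in BPB and 0.50 to 1.17 in controls, which nearly repeats the group, so calls lost under it say nothing of a cause. Medians of 14 of the 23, 15 of the 19 and 10 of the 16 called lists moved by over 1.5 times or turned sign without at least 1 library, and 2, 5 and 1 turned sign.

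Equal replicate numbers went with like deviations in BPB and BPAF but not in the controls, and a true pairing is not shown. Same-numbered pairs with a control had correlations of deviations from -0.40 (control 3 and BPB 3) to -0.079. Unlike numbers matched controls with BPB, at 0.335 (control 1 and BPB 2), 0.372 (control 2 and BPB 3) and 0.45 (control 3 and BPB 1). With the number as a block, limma called 19, 0, 0 and 0 genes (1481, 852 and 1735 with an unadjusted p under 0.05 where 0 were called), and 23, 19 and 17 lists passed. In BPAF against BPB the block in 6 libraries gave 0 genes (1788) and 16 lists, and apart from the MHC class II list, gained in 9 libraries, the blocks changed no list call there.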

Other observations

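Of the tests below, the scaling test and the splits of the libraries, apart from their sorting by pairs parted, were set before their result was seen, and all others were chosen after it, as were the genes named in the next paragraph.

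Single libraries stood apart within their groups. The interferon list averaged 6.18 log2(FPKM + 1) in control 1 and 1.88 to 3.31 in the other 8 libraries, and Isg15, a ubiquitin-like interferon-induced protein gene, had 457 FPKM in control 1. Mitochondrially encoded genes averaged 12.7 in control 3 and 10.8 to 12.1 elsewhere. Adipocyte genes averaged 0.77 in BPAF 2 and 2.39 to 4.57 elsewhere, and BPAF 2 had the highest mean of the mitotic list (3.44) and of the DNA replication list (4.03). Gland genes averaged 5.49 in BPAF 3, 4.09 in BPB 3 and 1.24 to 3.12 in the others.

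Clock genes moved in part. Nr1d1, Dbp and Plxnb1 were higher in all 6 exposed libraries than in any control, as was Slc5a11, a sodium-coupled transporter gene (0.18 ± 0.0161 FPKM in control, 9.92 ± 4.67 in BPB, 22.5 ± 32.1 in BPAF). Arntl, the core activator of the clock, and Per2 differed from control by -0.27 and -0.89 in BPB and did not pass (limma, adjusted p = 0.720 and 0.391). Sprr2f, a copy-rich gene of uncertain value, averaged 2994 ± 807 FPKM in control, 180 ± 151 in BPB and 505 ± 467 in BPAF, without passing in BPB (limma, adjusted p = 0.206). Lists with too few tested genes had medians in BPB and BPAF against control of -0.43 and 0.19 for ovary and corpus luteum, -0.09 and 0.64 for oviduct, 0.60 and -0.21 for erythrocytes and -0.31 and -0.12 for eosinophils.

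Bladder genes were high in the 3 BPB libraries and in BPAF 1, with Upk1a at 636 FPKM in BPB, and RNA of urinary bladder in these 4 libraries is a candidate explanation. Of 261 genes called higher in BPB outside the added lists, 77.4% had BPAF 1 as the highest BPAF library, where chance gives 33.33%, but the genes are not independent, and bladder RNA in BPAF 1 and a wrong label on it predict the same and cannot be told apart by this share. Of 69 genes called lower in BPB, BPAF 1 was the lowest BPAF library for 20, or 29.0%. A wrong label would predict a share above chance, but all 69 were also lower in BPAF than in control, which weakens the contrast. BPAF 1 lay below every BPB library for 74.7% of 229 genes called lower in BPAF 2 and 3 than in BPB. These genes were picked for high values in the same BPB libraries, so the 25% that equal ranks give is no measure of chance. It lay below pairs of BPB libraries for 86.2%, 72.1% and 70.5%, where the held-out BPB 1, 2 and 3 did for 79.6%, 24.8% and 21.1%. The shares for BPB 2 and 3 go against a wrong label, which stays open only because BPB 1 lay below the others almost as often as BPAF 1. The correlation of BPB 1 and BPAF 1 across genes was the highest of all pairs of libraries (0.951, next 0.941 for BPB 2 and 3). This cannot decide on a wrong label, since both share a trend with gene length with control 3. Control 3 correlated with BPAF 1 at 0.888, and with controls 1 and 2 at 0.874 and 0.854. Against a wrong label goes the smooth muscle mean of 6.36 in BPAF 1 (7.50 to 8.09 in BPB). The lower urinary tract mean was 1.34 in BPAF 1 (2.77 to 3.29 in BPB). That list was written after the values were seen, so its mean is no independent evidence on the label. The urothelial score of 5.61 in BPAF 1, against 5.84 to 6.68 in BPB, goes against an effect of BPB as the source, but it is the score of 1 library whose label is itself in doubt, so that effect is not excluded.

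The estrogen-induced list was lower in BPB and BPAF than in control by camera in limma (medians -1.72 and -1.19), with 3 and 0 of 27 genes called, and did not pass with an estimated correlation (adjusted p = 0.505 and 0.247) or by fry (adjusted p = 0.227 and 0.280). Dilution by other tissue cannot be decided by the stroma list, which holds fibroblast genes that other tissue can bring. Its median was -0.0945 (quartiles -0.61 to 0.93) in BPB, while the estrogen-induced list had -1.72. In BPAF 2 and 3, with urothelial means of 0.66 and 0.56, the estrogen-induced mean was 4.84 and 2.93, against 5.14 to 6.05 in controls. Scaling of the controls is argued against as the whole cause, as the estrogen-induced list had a median of -1.98 in BPB under median-ratio scaling. A different stage of the estrous cycle may account for the pattern, with the luteal median above the estrogen-induced one by 3.06, but the labels do not give the stage, so stage and treatment cannot be told apart.

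Zbtb9, Ggnbp1 and Pnoc separated the controls from all 6 exposed libraries. Counted reads moved read for read from Zbtb9 to its overlapping neighbour with no other change are argued against. The gain of Ggnbp1 exceeded the loss of Zbtb9 by 15.08 RPM (SE 2.48), the pair together rising from 22.9 to 38 RPM. How reads in both genes were counted is not given, so other exchanges between the overlapping genes stay open. A batch or origin of the animals shared by the 6 exposed libraries could be the source, with 18 genes apart from the controls by over 1 log2 unit against a median of 1 and at most 41 (the BPB libraries) over 84 choices of 3 libraries. An effect shared by BPB and BPAF stays open as well, as 0 of the 3 genes were called between them by limma.

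The 6 libraries of a comparison allow 10 splits, too few for a share under 0.05. As many genes as the real value came from 1 split in BPB against control (351, highest other 2), 1 in BPAF against control (3, highest other 0) and 1 in BPAF against BPB (33, highest other 2). Of the 4 splits of BPB and BPAF that part all 3 same-numbered pairs, the real one gave 33 genes and 16 lists, and the others 0, 0 and 2 genes and 16, 17 and 10 lists. The other 6 splits part 1 pair and gave 0 or 1 genes and 7 to 18 lists. As many lists came from 1 (23, highest other 17), 2 (19, highest other 21) and 7 splits (16, highest other 18). In the joint test 1 of 100 splits drawn from 280 gave as many genes (116, highest other 53). Of the 48 among them that part all 3 same-numbered BPB and BPAF pairs 1 did (highest other 53). The other splits, which part fewer pairs, gave at most 12 genes. The splits with 53 and 32 genes kept the 3 BPB libraries together, and that with 12 kept the 3 controls together. They hold part of the real groups, so the sorting by pairs does not show that pairing set these counts. With a replicate block the joint test called 0 genes in limma, with 1735 at an unadjusted p under 0.05. Chance is argued against for the count without a block but is not excluded. That count was 0 without control 1 and 1 without BPB 2 or BPB 3.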
